A study of Homo sapiens with 4 samples.

How the data were processed

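Total RNA from the human myeloma cell lines MM.1S and KMS-11 was measured on 4 one-colour Agilent expression arrays, 1 per group. Per the labels, each line carried either a control named Scr or the microRNA miR-7-5p, the cells were grown for 48 h in RPMI1640 with fetal calf serum, RNA was extracted with TRIzol, and it was labelled with Cy3. The labels give no expansion of Scr and do not say how the transduction was done. Per the file headers, the arrays share 1 design, 1 slide and 1 scan. No array is pooled and none is a replicate of another.

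The deposited scanner files hold, per the file headers, fluorescence intensity per spot as processed by Agilent Feature Extraction 12.0.3.1: the background was subtracted and spatial trends were removed within each array, and low values were replaced by a surrogate. Their values were not scaled between arrays. The deposited value table holds log2 values whose making no header or label records. Compared with the scanner files, its differences between arrays matched log2 of the processed intensity raised to at least 1, less the array's 75th percentile, with each probe then centred on its median over the 4 arrays. For the MM.1S pair 99.96% of 58201 probes matched within 0.001 log2. For the KMS-11 pair only 0.01% did, because all differences were shifted by a constant 0.00206 log2 (0.000923 in MM.1S). With each pair's constant removed, 99.96% matched within 0.001 in both. The percentile behind the table thus differed slightly from the one computed here, and its exact definition was not recovered. A record made before this check, that over 99% of probes match within 0.001, thus holds for KMS-11 only once the constant is removed. The column medians were 0.09 and 0.19 in MM.1S (Scr, miR-7) and −0.09 and −0.11 in KMS-11. The table served as an alternative and not as the main values.

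Here, the processed intensity was taken to log2 and the array's 75th percentile over all 58201 non-control probes was subtracted. Replicate spots of a probe were averaged after leaving out spots with the scanner's outlier marks, and 1 probe stood for each gene. A probe counted as detected where the scanner called it well above background. Because under 50% of probes were detected on each array, a 75th percentile over probes detected on all 4 arrays was also tried. The percentile over all probes was kept because it was the choice fixed in advance. Symbols came from the array files and from a RefSeq table (GRCh38.p14) used only for names: 33536 probes matched by accession, 4384 by symbol and 225 by an older symbol, and 20056 kept the name in the file. Positions are those of the probes in the array files (hg19).

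Within a line, 1 miR-7 array was compared with 1 Scr array, so no test and no p-value were possible. Genes were counted at 2-fold and 1.5-fold among those detected on at least 1 of the line's arrays. Values below the array's floor were raised to it, so folds from raised values are lower bounds. Across lines, limma 3.58.1 fitted cell line and miRNA as additive terms to the 21735 genes detected on at least 2 arrays, with 1 residual degree of freedom, moderated variances and Benjamini-Hochberg adjustment at 0.05. The SE given for a gene comes from that fit, and the SD given beside it is that of its changes in the 2 lines. Because each line holds 1 pair, a difference in response between lines could not be tested.

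The 24 gene lists were fixed in advance too. For each, the median change over members detected on all 4 arrays was placed among 10000 random lists of the same size matched on mean level in 20 bins, as a description of these arrays. Camera (limma) tested each list across lines with a preset inter-gene correlation of 0.01. The planned search for miR-7 seed sites in 3′ untranslated regions could not be run, because no transcript sequences were available. It was replaced, after the files were seen, by a search for the seed-match words in the 60-base probe sequences. Every 7-base word held by at least 20 genes was ranked by z. This is the difference in mean change from other genes, scaled for the number of genes with the word, without matching on level.

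Genes named in the text follow a rule fixed in advance: the 10 most negative and 10 most positive mean changes among genes changed 2-fold the same way in both lines, the 5 extremes per line and direction, the 4 most changed members per list, published miR-7 targets changed 1.5-fold in both lines, the 3 extremes among genes detected in 1 state only, the 6 most different genes per direction between lines with the myeloma translocation genes, and the 10 most negative genes with an 8-base site, here read from the probe. Only genes with an approved-style symbol were eligible, and genes on the Y chromosome, XIST and TSIX were left out. Not every gene that the rule picks is reported. Other genes are named as chosen afterwards.

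The methods were tested on simulated data. For the comparison across lines over 21735 genes, with 50 genes changed at each size, limma called 0 at a log2 change of 0.5, 0 at 1, 8 at 2 and 39 at 3, with 3 false calls. For the comparison between lines over the same genes, 2885 of 2891 genes simulated with a log2 difference of at least 2 were called, and 57 calls had the opposite sign to the simulated one. A list of 20 genes lowered by 0.5 had a camera p of 1.39e-14 (limma), and 4 of 100 unchanged lists had a camera p under 0.05. The simulated noise was independent between genes, so these values do not cover lists whose genes vary together. A word whose 68 genes were lowered by 0.2 ranked 1 of 12630.

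Settings chosen before the data were examined were normexp background correction with an offset of 50, quantile normalization, the percentile over detected probes, the deposited table, no filter, a filter for detection on all 4 arrays, the mean of a gene's probes, an intensity trend in the variance prior, the model without line or without miRNA, each line left out, and an estimated inter-gene correlation. Added after the data were seen were scaling to 8 spike-in probes, leaving out probes with a GA repeat, leaving out uneven spots (SD of pixels over their mean above 0.3), and no floor. The number of arrays limits the precision: replicate spots of 300 probes on an array had a median SD of 0.0558 log2 or less, but this covers the array and not the cultures. R 4.3.3, data.table (1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used.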

Results

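Gene expression was measured in 4 cultures of the human myeloma cell lines MM.1S and KMS-11, with 1 array for each of MM.1S Scr, MM.1S miR-7, KMS-11 Scr and KMS-11 miR-7. The study's stated purpose was to find genes with decreased expression after transduction with miR-7-5p. There were no replicates within a group. On the arrays in that order, 29199, 28567, 29716 and 29680 spots lay well above background, which corresponds to 45.96%, 44.89%, 46.82% and 46.78% of probes. The 75th percentile of the processed intensity was 49.13, 43.57, 56.01 and 56.97, and no spot was saturated. Mature miR-7-5p itself was not measured, so the arrays give no direct check of the transduction. The host transcript MIR7-3HG was not detected on any array.

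The first comparison was miR-7 against Scr within each line. In MM.1S, 400 genes were 2-fold or more lower on the miR-7 array and 412 were 2-fold or more higher, of 21056 genes counted. Among the 19408 genes detected on both arrays the counts were 327 lower and 285 higher, and 74 of those 285 had a probe with 7 or more alternating G and A bases, a feature of 1.39% of all these genes. At 1.5-fold, 1833 genes were lower and 1528 higher. The split in MM.1S depended on the scaling: it was 268 lower and 587 higher with the 75th percentile over detected probes, 993 and 203 with spike-in scaling, and 137 and 28 with normexp background correction. The median change of all genes moved with it, from −0.06 to 0.05 and −0.31 under the first 2 of these, so changes are relative to the array's 75th percentile. In KMS-11, 109 genes were lower and 81 higher of 21430 counted. Among the 20061 genes detected on both KMS-11 arrays, 58 were lower and 30 higher. Over all genes counted in KMS-11, 81 were lower and 110 higher with the percentile over detected probes, and 83 and 109 with spike-in scaling. With normexp background correction 11 were lower and 8 higher, and with no floor for dim values 256 and 200. The SD of the log2 change over genes was 0.41 in MM.1S and 0.26 in KMS-11.

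In MM.1S the gene with the most negative change detected on both arrays was POLE4, followed by CA8, CXCL10, COXFA4 and UHRF1. CXCL10 (chromosome 4, 76942934 to 76942993) was 6.3-fold lower in MM.1S and 4.71-fold lower in KMS-11, where it was detected with Scr only. Its undetected KMS-11 value lay just above the floor, so 4.71-fold is not a bound. The second probe of CXCL10 differed by −2.40 and −2.02 log2. UHRF1 (chromosome 19, 4962065 to 4962124) was 4.09-fold lower in MM.1S and 1.5-fold lower in KMS-11. CA8 (chromosome 8, 61102451 to 61102510) was 6.5-fold lower in MM.1S, on an uneven spot. The most positive changes in MM.1S were those of FAM229B and RAP2C-AS1, each 5.36-fold higher, and of DYNC2H1, 4.78-fold higher, DYNLRB2, 4.68-fold higher, and SYT11, 4.4-fold higher. The spot of RAP2C-AS1 was uneven. With normexp background correction these 5 changes were 0.64, 0.56, 0.49, 0.98 and 0.39 log2, all under 2-fold, and that of CA8 was −0.71. That setting adds an offset of 50 to each intensity, where the arrays' 75th percentiles were 43.57 to 56.97. It shrinks changes of genes near or below that level, so it cannot tell whether such changes hold. In KMS-11 the extremes other than POLE4 included NBR2, 4.61-fold lower, MAP1B, 4.44-fold lower, ALCAM, 3.25-fold lower, and PCDHA5, 2.93-fold lower. On the higher side were ARGFXP2, 16.3-fold higher, AASS, 11.4-fold higher, TOB1-AS1, 7.04-fold higher, MED28, 3.9-fold higher, and MYH8, 3.14-fold higher. NBR2, MAP1B, ARGFXP2, AASS, TOB1-AS1 and MED28 lay on uneven spots. Other probes of NBR2, MAP1B and TOB1-AS1 differed by 0.08, −0.34 and 0.34 log2 in KMS-11, so the folds of these 3 genes were not seen by a second probe. With normexp background correction the KMS-11 changes of ALCAM, PCDHA5 and MYH8, on even spots, were −0.33, −0.34 and 0.38 log2. These genes lay below the 75th percentile on both KMS-11 arrays, so the same limit holds. Over the alternative settings those of ARGFXP2, AASS and MED28 went down to 1.621, 2.275 and 0.603 log2.

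The comparison of miR-7 with Scr across both lines asked which genes were lower in both. With limma, 0 of 21735 genes passed an adjusted p of 0.05 in either direction, and the smallest adjusted p was 0.445. At an unadjusted p under 0.05 there were 1342 genes lower and 1078 higher. With an intensity trend in the variance prior, 71 genes lower and 12 higher passed. Without a filter on dim probes 5 and 8 passed, and with spike-in scaling, where all genes shared the same variance, 204 and 92. The other alternatives for this fit gave 0. By size alone, 18 genes were 2-fold or more lower in both lines and 7 were higher, of 19430 genes counted in both. With normexp background correction these counts were 6 and 0, and with no floor for dim values 22 genes were higher. Independent lists of the same lengths would share 1.19 and 0.6 genes. Another 4 genes were changed 2-fold in opposite directions. Across 18034 genes detected on all 4 arrays, the changes in the 2 lines had a Pearson r of 0.418 and a Spearman rho of 0.444, and 67.2% of genes had the same sign. Genes are not independent replicates, so no p is given for these values.

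**Figure D1:**
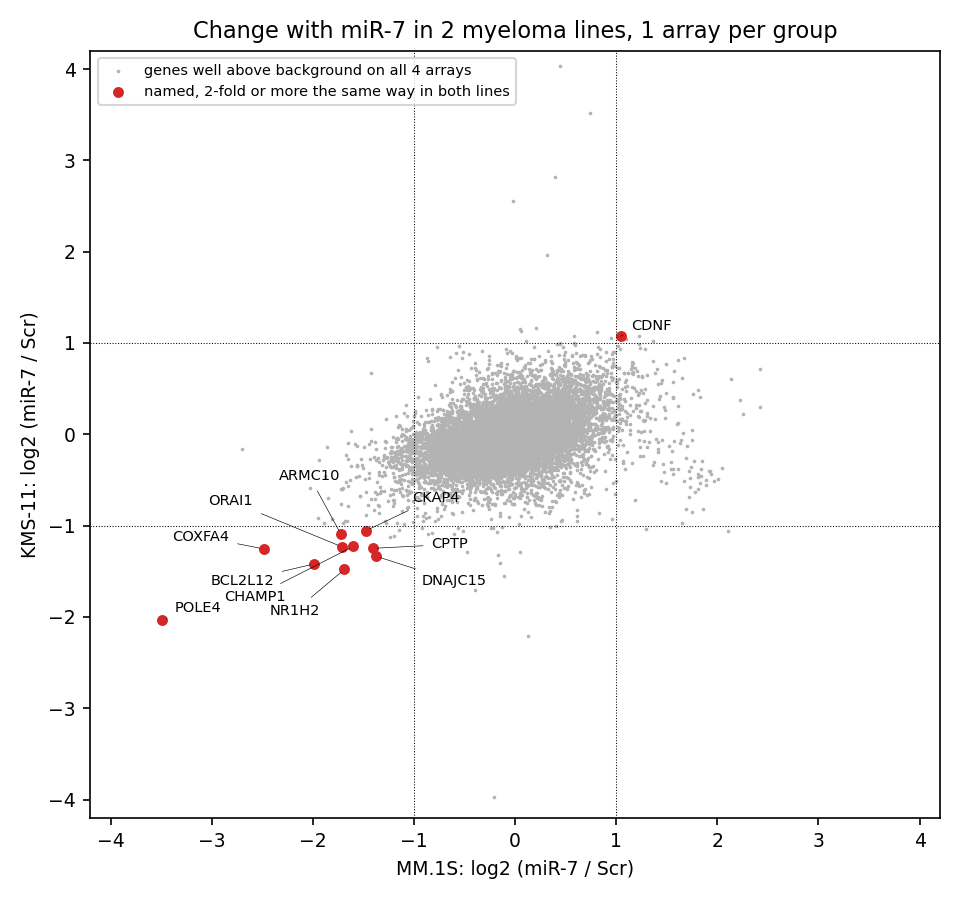
Log2 change with miR-7 against Scr in MM.1S (x axis) and in KMS-11 (y axis); each grey point is 1 gene detected on all 4 arrays, dotted lines mark 2-fold, and the genes named by the rule for both lines are red. POLE4 lies farthest toward the lower left, at −3.49 and −2.04.

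Of the genes lower by 2-fold in both lines, 14 had a symbol and were detected on all 4 arrays. POLE4 (chromosome 2, 75187247 to 75196568) had the most negative mean change, −2.76 (SD 1.03, SE 0.395, n = 2 lines, limma adjusted p 0.445). It was 11.2-fold lower on the miR-7 array in MM.1S and 4.1-fold lower in KMS-11, and its second probe differed by −3.29 and −1.96. COXFA4 (named NDUFA4 on the array, chromosome 7, 10973185 to 10973244) was 5.6-fold and 2.39-fold lower, with a mean change of −1.87 (SD 0.87). BCL2L12 (chromosome 19, 50177097 to 50177156) was 3.96-fold and 2.67-fold lower, and its second probe differed by −1.67 and −1.26. NR1H2 (chromosome 19, 50882329 to 50882388) was 3.22-fold and 2.79-fold lower. ORAI1 was 3.28-fold and 2.35-fold lower, CHAMP1 3.03-fold and 2.34-fold, ARMC10 3.3-fold and 2.14-fold, DNAJC15 2.6-fold and 2.52-fold, CPTP 2.65-fold and 2.38-fold, and CKAP4 2.78-fold and 2.08-fold. These 10 genes had adjusted p values of 0.445 in limma, and all 10 passed both with the intensity trend and with spike-in scaling. With spike-in scaling limma's prior degrees of freedom were infinite, so all genes shared the same variance. Passing there depended on the size of the mean change alone. The only named gene 2-fold higher in both lines and detected on all 4 arrays was CDNF, 2.06-fold in MM.1S and 2.11-fold in KMS-11. With normexp background correction the mean change was 0.25 for CDNF, −0.72 for NR1H2 and −0.78 for DNAJC15, so these did not reach 2-fold on average there.

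**Figure D2:**
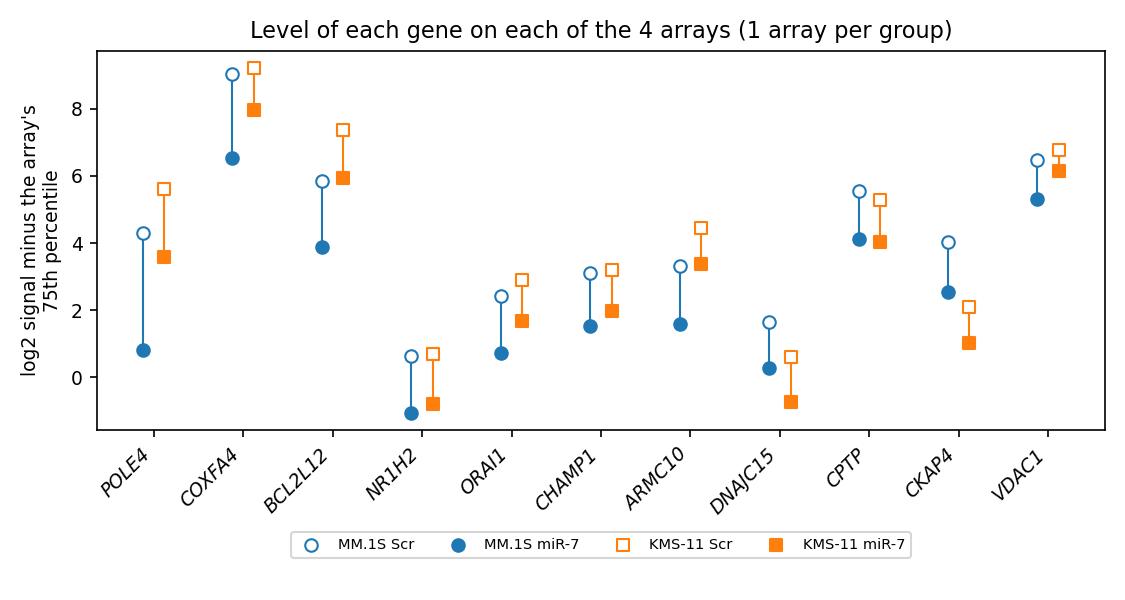
Level of each gene (y axis, log2 intensity less the array's 75th percentile) on each of the 4 arrays for the 10 genes named as lower in both lines and for VDAC1; open symbols are Scr and filled symbols miR-7, and a line joins the 2 arrays of a cell line. The filled symbol lies below the open one for every gene in both lines, from 4.30 to 0.81 for POLE4 in MM.1S.

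Some genes were detected in 1 state only in both lines: 107 genes were detected with Scr only and 58 with miR-7 only. Their folds are bounds where the undetected value was raised to the floor. The bounds hold in the main processing only. With the largest bounds among named genes, CRTAP was at least 2.3-fold lower in MM.1S and 1.51-fold lower in KMS-11. FA2H was at least 2.11-fold and 1.63-fold lower, and PRR20B at least 1.64-fold and 2.08-fold. Over the alternative settings, the mean log2 changes of these genes over the lines were as small as −0.118, −0.107 and −0.066. In the other direction TMEM123-DT was at least 2.57-fold higher in MM.1S, and it was 1.88-fold higher in KMS-11. ALOX15 was 2.11-fold higher in MM.1S and at least 1.56-fold in KMS-11, and GLYATL1-AS1 2.25-fold and at least 1.43-fold. The undetected values of TMEM123-DT in KMS-11 and of ALOX15 and GLYATL1-AS1 in MM.1S lay above the floor, so those folds are not bounds. Over the alternative settings the mean log2 changes of TMEM123-DT, ALOX15 and GLYATL1-AS1 went down to 0.165, 0.115 and 0.136.

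Whether genes with a match to the miR-7 seed stood apart was read from the probe sequences, which cover 60 bases of each transcript and not its whole 3′ end. The median change of the 36 genes whose probe held the 8-base match GTCTTCCA was −0.30 in MM.1S and −0.26 in KMS-11, against −0.06 and −0.04 for 17442 genes without any match. These medians lay at percentiles 0.01 and 0 of 10000 random lists. The classes of match were not exclusive, although the plan took the best site per gene: genes with the 8-base match count again under each shorter match. For the 7-base match to seed positions 2 to 8 (120 genes) the medians were −0.20 and −0.17, both at percentile 0. The median of genes whose probe held this 7-base word, less that of genes without a match, was −0.135 in MM.1S and −0.134 in KMS-11. It was −0.061 and −0.052 with normexp background correction, whose offset shrinks changes of dim genes. It was −0.034 in KMS-11 without a filter on dim probes. For the 7-base match that ends in A they were −0.13 and −0.09, at percentiles 3.48 and 0.7, and for the 6-base match −0.11 and −0.04, at percentiles 0.01 and 17.44. Over 12630 words of 7 bases, z placed GTCTTCC at rank 1 toward lower values in MM.1S and by the mean of both lines. In KMS-11 it ranked 3. By mean difference alone, AACATGC was lower in MM.1S (−0.241 against −0.226) and GATCACC in KMS-11 (−0.193 against −0.142). Among the 10 genes with the 8-base word that were lowest on average in both lines were COXFA4, CHAMP1, CPTP, UBXN2B, SAV1, PRKCB, OSBPL11, ARPC1A and CCT4. UBXN2B was 2.36-fold lower in MM.1S and 1.58-fold lower in KMS-11, SAV1 1.86-fold and 1.68-fold, and CCT4 1.6-fold and 1.27-fold.

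The gene lists asked whether published miR-7 targets and myeloma-related processes stood apart. The 31 detected genes on the list of published miR-7 targets had a median change of −0.33 in MM.1S (percentile 0.03 of random lists) and −0.29 in KMS-11 (percentile 0), with 24 lower in both lines and 2 higher in both. The camera adjusted p was 0.00015 with the preset correlation and 0.795 with an estimated one. None of its genes passed in limma, whether adjusted over all genes or adjusted over the list alone. Among its genes at least 1.5-fold lower in both lines were POLE4 and VDAC1. VDAC1 (chromosome 5, 133307902 to 133307961) was 2.21-fold lower in MM.1S and 1.51-fold lower in KMS-11. PSME3 was 3.09-fold and 1.41-fold lower. IGF1R and IRS1, chosen here after their values were seen, had changes of −0.12 and 0.60 in MM.1S and 0.04 and −0.12 in KMS-11.

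Of the 24 lists, 7 passed camera's adjusted p of 0.05 with the preset correlation, all toward lower values. With an estimated correlation 0 of them did, at a camera adjusted p of 0.795. That test used the fit's 1 residual degree of freedom and had little power. The estimates were 0.818 for G1/S, 1 for G2/M, 1 for MYC, 0.659 for the proteasome, 0.602 for cholesterol and 0.505 for the reference genes. These lie far above the preset 0.01. With 1 residual degree of freedom, however, each estimate reflects only how many of a list's genes differed between the lines in the same direction. It cannot tell a shared difference between lines from genes that vary together. Whether the camera p values of these lists are too small therefore stays open. The G1/S and replication list had medians of −1.13 in MM.1S and −0.21 in KMS-11 (percentiles 0 and 0.21, adjusted p 1.12e-06 in camera), with 20 of 22 genes lower in both lines. Its most changed members were CCND2, GINS1, CDT1 and CDC6, at −1.34, −1.56, −1.56 and −1.50 in MM.1S and −0.65, −0.35, −0.34 and −0.14 in KMS-11. The G2/M list had medians of −0.60 and −0.08 (percentiles 0 and 35.58, camera adjusted p 0.000271). The MYC and ribosome biogenesis list had −0.55 and −0.33 (percentile 0 in both, camera adjusted p 5.48e-08), and all 20 of its genes were lower in both lines. The proteasome list had −0.31 and −0.14 (percentiles 0.56 and 13.91, camera adjusted p 2.55e-05), with 31 of 33 genes lower in both. The cholesterol synthesis list had −0.46 and 0.01 (percentiles 0.02 and 94.55, camera adjusted p 0.0118). The reference genes also passed (−0.23 and −0.13, camera adjusted p 0.0322), yet among random lists of the same level their percentiles were 19.8 and 39.52. Over all genes, the brightest eighth had median changes of −0.18 and −0.12. The proteasome, cholesterol and reference lists no longer passed with quantile normalization, and the reference list failed also with the percentile over detected probes and with spike-in scaling. Whether any list differed between the lines was not tested.

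**Figure D3:**
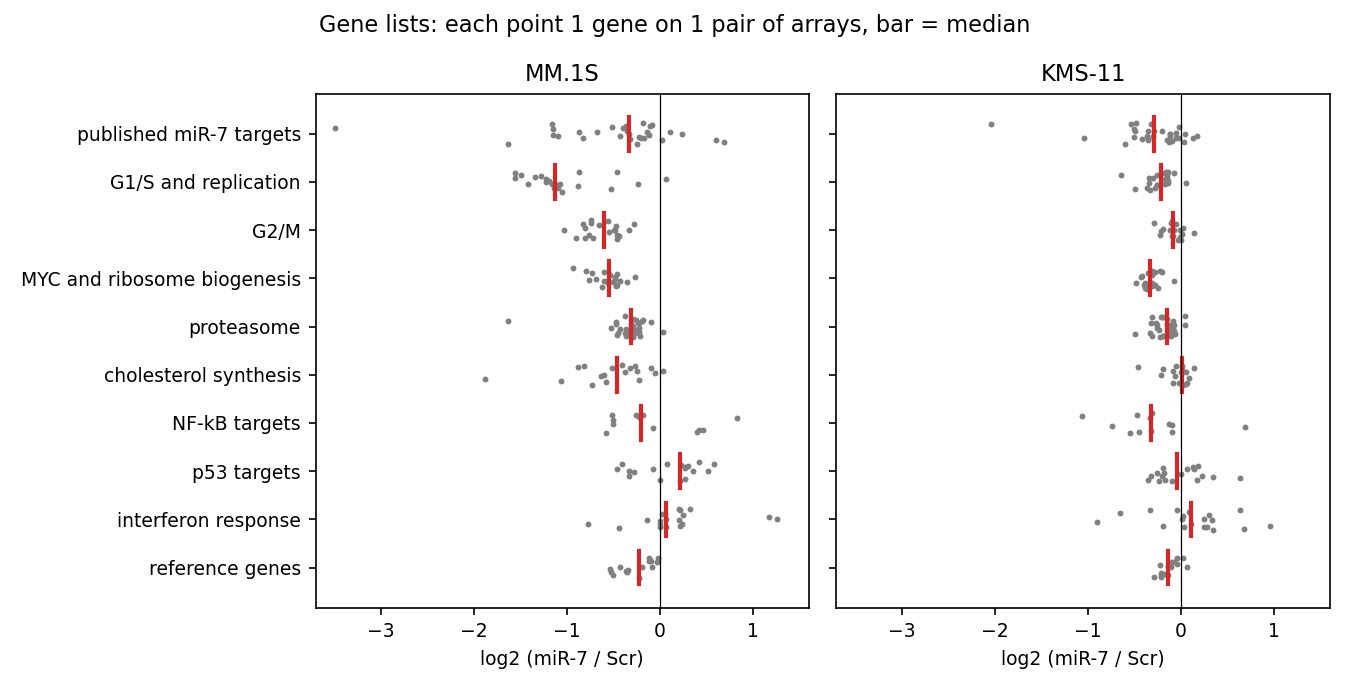
Log2 change with miR-7 against Scr (x axis) in MM.1S and in KMS-11 for 10 gene lists; each point is 1 gene detected on all 4 arrays and the red bar is the list's median. The G1/S and replication list has its median at −1.13 in MM.1S and at −0.21 in KMS-11.

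The other lists did not pass, although with normexp background correction the NF-kB, interferon and plasma cell lists (camera adjusted p 0.0219 each) and the chromatin list (0.0126) did, and the interferon list did with detection on all 4 arrays (0.027). The NF-kB targets had medians of −0.20 and −0.32 (percentiles 20.56 and 0, camera adjusted p 0.132), and the interferon response genes 0.07 and 0.10 (percentiles 90.84 and 98.83, camera adjusted p 0.0923). The p53 targets had 0.22 and −0.05 (percentiles 99.99 and 48.82, camera adjusted p 0.405). The IGF, PI3K, AKT and mTOR list had −0.09 and −0.05 (camera adjusted p 0.405), the RAS and MAPK list −0.14 and −0.01 (0.599), the BCL2 family −0.10 and −0.12 (0.63), the chromatin regulators −0.23 and −0.12 (0.125) and hypoxia −0.27 and −0.03 (0.236). The endoplasmic reticulum chaperones had −0.05 and −0.10 (camera adjusted p 0.63), the ATF4 targets −0.02 and −0.11 (0.946), plasma cell identity −0.09 and −0.15 (0.599), the small RNA machinery 0.08 and −0.03 (0.596) and the myeloma translocation genes −0.31 and −0.03 (0.599). The lists of T and NK, B, and stromal and erythroid cells held 4 detected genes each, with medians of −0.23 and −0.13, 0.11 and −0.10, and −0.01 and −0.01, and camera adjusted p values of 0.236, 0.63 and 0.773. The myeloid list held 1 gene detected on all 4 arrays and was not summarised. In limma, genes that passed when adjusted over the list alone included CXCL10 in the interferon list and ITGAM, named after its value was seen, in the myeloid list of 2 tested genes, both toward lower values. Over all genes none passed in any list.

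The last comparison was between the lines, with miRNA as a term in the limma fit. At an adjusted p of 0.05, 5489 genes were lower and 6251 higher in KMS-11 than in MM.1S, and with spike-in scaling these were 2591 and 10570. Among genes detected on all 4 arrays, those most different toward MM.1S were IGLL5, at −14.08 log2, GSTP1, at −12.68, LAMP5, at −9.88, CD44, at −9.03, CCL3L3, at −8.84, and ICAM3, at −8.56. Toward KMS-11 they were GSTM3, at 7.64, FOXO6, at 7.59, PFKP, at 7.15, COL9A3, at 6.59, NFIC, at 6.57, and AGPAT2, at 6.53. Sizes depended on the processing: CD44 was at −4.76 with the mean of its probes, ICAM3 at −5.91 and COL9A3 at 3.98 with normexp background correction, and NFIC at 3.52 with the mean of its probes. Over the alternative settings FOXO6 went down to 4.435 and the size of LAMP5 fell to −6.618. The limma adjusted p values of the 12 genes lay between 0.000344 and 0.000432. Among the myeloma translocation genes, FGFR3 (chromosome 4, 1810363 to 1810422) was detected only on the KMS-11 arrays and was at least 7420-fold higher there in the main processing (limma adjusted p 0.000681), with a log2 difference of 9.41 with normexp background correction. NSD2 (chromosome 4, 1983546 to 1983605) was 3.72-fold higher in KMS-11 (SE 0.215, limma adjusted p 0.00576). MYC was 1.74-fold higher in KMS-11 (limma adjusted p 0.0162) and CCND3 1.61-fold higher (0.0375). CCR1 was 9.25-fold lower in KMS-11 (limma adjusted p 0.00211) and ITGB7 2.01-fold lower (0.00868). CCND3 no longer passed with quantile normalization, with the percentile over detected probes or with miRNA left out, and ITGB7 with quantile normalization or spike-in scaling. CCND2 and MAF did not pass (limma adjusted p 0.323 and 0.13), but CCND2 did with spike-in scaling (0.00664) and MAF, lower in KMS-11, with the intensity trend (0.0185), and CCND1 was not detected on any array.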

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

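All tests in this part were chosen after the results were seen. With 1 array per group, a difference in response between the lines could not be tested, so the differences below are untested. Each gene was detected in both lines and was picked out because the miR-7 array lay above Scr in one line and below it in the other, by more than 0.112 log2 in each, which is 2 times the largest median SD of replicate spots. CCR1 changed by −0.14 in MM.1S and 0.60 in KMS-11, a difference of 0.741. IGLL5 changed by 0.21 and −0.48, a difference of −0.686. NBR2 changed by 0.12 and −2.21, a difference of −2.329. BLK changed by 0.32 and −0.14, a difference of −0.465. Among the 147 genes that the naming rule picks, these 4 met the condition. The limit covers replicate spots within an array and not the spread of a difference between arrays. The MM.1S changes of all 4 genes lay within the SD over genes in that line (0.41). That of BLK in KMS-11 also lay within the SD there (0.258). Opposite responses are therefore not shown for these genes. Probes with a GA repeat differed by −2.078 as a group.

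The GA-repeat probes were 39 probes with an alternating run of at least 10 bases, detected on at least 3 arrays. Their median change was 1.70 in MM.1S, with 38 of 39 higher, and −0.38 in KMS-11, with 38 lower. The change in MM.1S went up with the length of the run, from −0.07 at 6 bases or fewer through 0.41 at 8 to 9 and 1.61 at 10 to 11 to 1.81 at 12 or more. Of the 285 genes detected on both arrays and 2-fold higher in MM.1S, 26% had a probe with 7 or more alternating G and A bases, against 1.39% of all genes. Against array scaling, the probes stayed 1.816 above the median of all genes under quantile normalization. The median in KMS-11 was −0.379, the opposite direction, so the change was not common to both lines. This restates the pattern and is not a separate test of a miR-7 effect. A candidate explanation is hybridisation to the repeat itself and not to the named genes: 18 other probes of 7 of these genes had a median MM.1S change of −0.109. What brought the repeat to the arrays in unequal amounts is open, and a miR-7 effect particular to MM.1S was not tested.

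Of the 20 picks made as the 5 most changed genes per line and direction, 8 lay on uneven spots, while at most 0.43% of detected probes on an array did. For NBR2, MAP1B and TOB1-AS1, other probes of the gene were detected, and the change largest in size among them was −0.342. A spot defect may therefore account for the KMS-11 changes of these 3 genes, and for the difference between lines given for NBR2. For POLE4, CXCL10 and UHRF1, whose spots were even, the other probes changed by at least 1.957 in size in the line for which each gene was picked. The 5 remaining uneven genes had no second detected probe and stay open. No biological explanation was tested for CCR1, IGLL5 and BLK.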

How the results depend on the processing

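Spike-in scaling, the sets without GA-repeat probes or uneven spots, and the run without a floor were chosen after the data were seen. Of 1959 values for named genes under alternatives, 1836 stayed close to their value or on the same side of the threshold, and 9 reversed. Of 322 list medians, 280 did and 25 reversed. These counts do not measure stability. No gene passed across lines in the main fit, so a mean change that kept its sign and failed again counted as staying, whatever its size. CDNF counted with 1.06 in the main fit and 0.25 with normexp. With a line left out only the sign was compared, and having no floor leaves these values unchanged by design. Except where stated, the cause was not tested.

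In MM.1S the count of 2-fold lower genes (400) became 137 with normexp, 993 with spike-in scaling, and 609 both with the deposited table and with no floor. That of higher genes (412) became 28 with normexp, 203 with spike-in scaling, and 216 with detection on all 4 arrays, which counts fewer genes. In KMS-11 lower genes (109) became 11 with normexp, 36 with detection on all 4 arrays, and 256 with the table and with no floor. Higher genes (81) became 8, 17 and 200 in that order, and 50 without uneven spots. Genes lower in both lines (18) became 6 with normexp. Those higher in both (7) became 0 with normexp, 15 with the percentile over detected probes, 22 with the table and with no floor, 4 with detection on all arrays and 3 with spike-in scaling. In both the table and the run with no floor, dim values were not raised to the array's detection floor.

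Across lines, limma's calls (0 lower, 0 higher) became 5 and 8 without a filter, 204 and 92 with spike-in scaling, and 71 and 12 with the intensity trend. They stayed at 0 with normexp, quantile normalization, the percentile over detected probes, the table, detection on all arrays, the mean of probes, no floor, the model without line, and without GA-repeat probes or uneven spots. With spike-in scaling limma's prior degrees of freedom were infinite, so all genes shared the same variance and calls depended on size alone. The smallest adjusted p ranged from 1.74e-17 (spike-in scaling) to 1 (the model without line). Between lines, spike-in scaling gave 2591 lower and 10570 higher. The r between lines (0.418) became 0.097 without a filter and the rho (0.444) 0.178; the SD of the difference between lines (0.382) became 0.661 without a filter and 0.228 with normexp.

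The gap between genes with GTCTTCC and without a match (−0.14 in MM.1S, −0.13 in KMS-11) became −0.061 and −0.052 with normexp, and −0.034 in KMS-11 without a filter. The word's rank was 1 to 3 with a line left out. The number of lists past the threshold (7) became 11 with normexp, 4 with quantile normalization and 0 with an estimated correlation. In the last setting camera used the fit's 1 residual degree of freedom and had little power.

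List medians of the mean change reversed as follows. With quantile normalization, IGF and PI3K became 0.003, chaperones 0.043, ATF4 targets 0.083, plasma cell identity 0.034 and hypoxia 0.018. With the percentile over detected probes, the same lists became 0.023, 0.018, 0.034, 0.002 and 0.046, and the BCL2 family 0.013. With spike-in scaling, p53 targets became −0.059, small RNA machinery −0.078, B cells −0.076 and stromal −0.07. With normexp, small RNA machinery became −0.013, B cells −0.011 and stromal −0.02, and with the mean of probes small RNA machinery became −0.023. With each line left out, the p53 targets ranged from −0.046 to 0.218, cholesterol synthesis from −0.461 to 0.012, small RNA machinery from −0.032 to 0.078, B cells from −0.099 to 0.106 and stromal from −0.012 to −0.01. Among genes, the mean change with a line left out ranged from −0.75 to 0.06 for DERL3, from −0.143 to 0.322 for BLK, from −0.118 to 0.039 for IGF1R and from −0.119 to 0.6 for IRS1. BLK became −0.008 with spike-in scaling, and IGF1R 0.017 with quantile normalization and 0.045 with the percentile over detected probes. NBR2 in KMS-11 became 0.081 without uneven spots, where another probe stands for it, and the line difference of MAF became 0.215 with spike-in scaling.

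No paired analysis beyond the term for line was possible because each line has 1 pair of arrays. The slide as a block was not run because all 4 arrays lie on 1 slide, and the other choice of 3′ untranslated region was not run because no transcripts were available. Signal over background limits the rest: at most 46.82% of probes were detected on an array. Changes of genes with a value raised to the floor are bounds.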

Other observations

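The tests of signal trend and scaling for the G1/S genes were chosen after the result was seen; the tests on other cultures and on cilium genes were written beforehand. The families below were scanned without a list fixed in advance.

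The G1/S and replication genes had a median change of −1.13 in MM.1S. Against a trend of change with signal level, the median was −0.961 after the trend was removed (SD 0.42 over genes). Against array scaling, the gap between the list median and the median of all genes in MM.1S was −0.998 with quantile normalization and −1.118 with normexp. The percentile over detected probes and spike-in scaling shift each array by 1 constant. They cannot change this gap, which was −1.068 in both, and are no test of it. Removing the level trend took the proteasome list from −0.31 to −0.11 in MM.1S, and the published miR-7 targets from −0.33 to −0.24. In KMS-11 it took the proteasome list from −0.145 to −0.042 and the published targets from −0.291 to −0.188. The G1/S list went from −0.214 to −0.138 in KMS-11. Whether miR-7 or another difference between the cultures lowered the G1/S genes cannot be told apart, because there was 1 Scr culture of MM.1S.

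Of 118 families by symbol stem, the 67 detected histone genes had medians of −0.75 in MM.1S (percentile 0) and −0.03 in KMS-11 (percentile 99.78). The sign in KMS-11 flipped to 0.07 with quantile normalization, 0.03 with the percentile over detected probes and 0.03 with spike-in scaling, while the median in MM.1S lay between −0.996 and −0.60 over the scalings. The 16 intraflagellar transport (IFT) genes had medians of 0.35 in MM.1S (percentile 99.99) and 0.10 in KMS-11 (percentile 96.42), and the MM.1S median was 0.142 with normexp and 0.104 with spike-in scaling. Other families stood as far out: the 20 GOLGA genes had 0.33 and 0.07 (percentiles 100 and 97.89), and the 22 NUP genes −0.56 and −0.17 (percentiles 0 and 0.89), with 21 lower in both lines. The signs of both families held under the 4 other scalings, but the GOLGA median in MM.1S was 0.174 with normexp and 0.078 with spike-in scaling. GOLGA1, GOLGA3 and GOLGA5 changed by −0.081, −0.072 and −0.086 in MM.1S, and GOLGA2, GOLGA4 and GOLGA7 by 0.406, 0.233 and 0.113. The other GOLGA members, mostly higher there, carry GOLGA2P, GOLGA6 or GOLGA8 names. Whether their probes measure separate transcripts was not tested. A hypothesis, one of several that the scan could have prompted, was that genes of the primary cilium were higher as a class. On a separate list of 42 cilium genes, 38 were detected, with a median of 0.26 in MM.1S at percentile 100 and 0.13 in KMS-11 at percentile 99.99, and 28 were higher in both lines. With normexp the median of the list in MM.1S was 0.125, and with spike-in scaling it was 0.009, where that of all genes was −0.314. This may reflect a class effect, as a hypothesis only: it was tested on the same arrays. The 1441 long non-coding RNAs had medians of 0.06 and 0.05, and the 11892 protein-coding genes −0.10 and −0.06. With spike-in scaling the non-coding median in MM.1S was −0.19, and with the percentile over detected probes the coding medians were 0.018 and 0.002. With quantile normalization the coding median in KMS-11 was 0.003.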
